A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

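The deposited table covers 8 libraries of tRNA variants in budding yeast: 2 input libraries grown at 30 °C in medium lacking histidine, and 6 output libraries grown at 37 °C in the same medium with 1 M NaCl. Per the labels' protocols, plasmid DNA was extracted from the cells and the tRNA gene was amplified in 2 rounds of PCR before sequencing. Adapters were trimmed with cutadapt per the submitters' processing notes, which give no version. The other steps from read to genotype are not given in the sources used here. No molecular identifiers are described, so reads are not independent molecules.

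The deposited values used for testing are raw counts of reads per genotype, described by the authors in the file header as reads left after filtering. The lowest count is 9 in each input and 1 in each output. Genotypes lost from an output are therefore not analysed here, which limits how low a measured value can be. The authors' deposited natural log of fitness, written with its standard error, is relative to the reference genotype and combines the outputs. Its formula is not given in the sources used here, and it was used only for comparison.

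Genotype names were checked against the listed sequences, and 0 disagreed. Relative enrichment is the log2 change in a genotype's count from input to output, relative to the change of the reference, the *Saccharomyces cerevisiae* sequence. It was fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, quasi-likelihood test, two-sided), output against input, with each library's size set to 4 times its count of the reference. Genotypes needed at least 10 reads in each input, which left out 75 and kept 4100. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. The median standard error was 0.24 (log2). Values per output, with their SDs and signs over the 6 outputs, set each output against the mean of both inputs. The outputs thus share the error of the inputs, which these SDs and signs do not measure.

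The effect of a substitution in 1 background is the difference of 2 fitted values. A pairwise interaction is the departure of a genotype with both substitutions from the sum of the separate effects, and a third-order interaction is the change of a pairwise one when another substitution is added. Standard errors were combined and Benjamini-Hochberg adjustment was made over all tests of 1 kind. Means over backgrounds used the combined measurement errors and a normal distribution, adjusted over all combinations of that order. Additive, pairwise and third-order models were fitted by ridge regression, penalties 0.01 to 10, with R squared from 10-fold cross-validation over genotypes. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 was used for these steps. Tests of facing against other pairs used 100000 permutations, two-sided, for which the smallest p is 1e-05.

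Positions are counted from 1 at the 5′ end of the 72-nucleotide sequence, and a substitution gives the reference base, the position and the new base. The list of facing positions was written before the data were examined. It joins positions 1 to 7 with the positions that add up to 72 with them, and 27 with 43. It also joins the positions next to 27 and 43 in the same way, none of them varied here. In the deposited sequence positions 27 and 43 hold C and A, which do not form a base pair, so this entry of the list is an error. C27 lies opposite a G there, so C27U would turn a C-G pair into U with G. The list was kept as written. By it the reference itself has 1 mismatched pair, and only genotypes with C27U can have 0. The difference of facing and other pairs and the medians by mismatched pairs are also given for the acceptor stem alone, with 27 and 43 left out, an alternative chosen after seeing the data.

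Items to be named were fixed by rule before the data were examined: the reference, every substitution alone, the 3 highest and 3 lowest genotypes past the threshold with at least 100 reads in each input and the same direction in 6 of 6 outputs, every facing pair, the 5 most positive and 5 most negative other pairs, the 3 triples with the largest absolute mean, and genotypes restoring all facing pairs. No genotype above the reference met the rule.

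The first digit of an output's label matches the number of an input. Over 1359 genotypes with at least 50 reads in every library, each output's deviation from the output mean was correlated with the deviation of the input of its own digit. The 6 correlations, across genotypes, ran from 0.22 to 0.53, so the digits were taken to pair the libraries. With 2 inputs the deviations mirror each other, so this check cannot separate the 2 inputs' contributions. A fit with the digit as a replicate block is printed where it changes a call or moves a count by over 1.5 times. The header of the deposited table gives each output its own final optical density, 1.14 to 1.39, as that of parallel competition cultures, so the outputs were grown separately. Nothing says that the 2 inputs came from separate cultures, so p-values for output against input measure only the spread between these libraries, part of which may be technical.

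No libraries looked like copies. The most alike, outputs 22 and 23, had a chi-square of 1.10 per degree of freedom over genotypes. Outputs sharing a first digit gave 1.10 to 1.81, outputs with different digits 2.68 to 3.55, and the 2 inputs 3.73.

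The procedure was tested on simulated counts for 4100 genotypes. Dispersion was set to 3 values in turn, 0.06, 0.01 and 0.016, because the simulated standard errors did not match the measured ones; the last is edgeR's common dispersion, 0.016, rounded. In the additive simulation the median standard error was 0.339, 0.204 and 0.223, against 0.239 measured, so no value matched it. With 200 genotypes changed, 98%, 98% and 100% of losses of 2 log2 units were recovered, and 44%, 76% and 76% of losses of 1 unit. Losses of 0.5 were recovered in 2%, 48% and 34%, and gains of 0.5 in 0%, 38% and 22%. Unchanged genotypes made up 2.70%, 4.41% and 6.45% of calls. With additive effects and no interaction, 0, 3 and 0 substitutions were called in both directions, and 0% of pairwise and of third-order tests were called in each. An interaction of 1 log2 unit was estimated at 0.994, 1.02 and 0.975.

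The alternatives were TMM, total-count and DESeq2 size-factor scaling with the reference's change subtracted, DESeq2 1.42.0, limma 3.58.1 on log2 ratios with a pseudocount of 0.5, no filter or at least 100 reads in each input, a mean output count of at least 10, the replicate block, each library left out, medians for means, and the linear ratio scale. The limma fit counted the 6 ratios as independent although 3 outputs share each input. It thus understates the error of the inputs and may call too many. Added after seeing the data were the acceptor stem alone, also under each other alternative, and each input with its own outputs alone. Fits with 1 input, including those with an input left out, take their spread from the outputs. Their p-values and calls thus do not measure the spread between inputs.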

Results

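The series measured how 14 substitutions at 10 positions of a yeast arginine tRNA, alone and combined, changed the abundance of its carriers during growth. The gene, HSX1 (locus YNCJ0025W), encodes the tRNA with a CCU anticodon and lies on chromosome X from 538555 to 538626 in assembly R64. It is a noncoding gene of 72 nucleotides, and the deposited reference sequence is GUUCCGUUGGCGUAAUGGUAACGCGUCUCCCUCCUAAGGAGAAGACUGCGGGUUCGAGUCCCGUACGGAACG. The host strain was BY4742, a laboratory haploid, with its own HSX1 replaced by a drug-resistance cassette, so that the tRNA variant came from a plasmid. The table holds 4176 genotypes, 80.56% of the 5184 possible combinations. The 2 input libraries held 1281843 and 1353250 reads and the 6 output libraries 1241249 to 1559898. The reference made up 17.2% ± 1.08 (SD, n = 2) of input reads and 23.1% ± 0.716 (SD, n = 6) of output reads.

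The first question was how the variants fared against the reference at 37 °C in 1 M NaCl. Most fell: 3510 of 4100 genotypes (85.6%) were below the reference. The median log2 relative enrichment was -1.29, a ratio of output to input that was 0.410 of that of the reference. No genotype was called above it. For the lowest genotype by the naming rule, G1A+C46U+C66U+A69G+C71U, the ratio of output to input was 8.00% of that of the reference (log2 -3.64 ± 0.21, SD, n = 6, below in 6 of 6 outputs). U2G+G6U+C66A+A69G+A70U+C71U at -3.54 ± 0.22 and G1A+U2G+G6U+C46U+C66U+A70U+C71U at -3.54 ± 0.49 were next. The edgeR adjusted p-values of these 3 were 1.47e-11, 1.1e-10 and 8.3e-10.

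The count of 0 above the reference came from edgeR. At an unadjusted p under 0.05 there was 1, DESeq2 gave 0 and limma gave 5. The limma fit counted the ratios of all outputs as independent, although outputs share inputs. With the replicate block 5 were above and 3706 below. Those 5, chosen after their values were seen, were U2C, U2C+C46U, U2C+G6A, U2C+C46U+C66A+A70U and G6U+A43C+C46U+C66A+A69G, with blocked log2 values of 0.12, 0.17, 0.16, 0.48 and 0.49. Their blocked edgeR adjusted p-values were 0.0234, 0.0146, 0.0251, 0.0469 and 0.0492. The 2 with the largest values had few input reads, 33 and 31 for the former and 26 and 22 for the latter. Limma called 4 of these 5 genotypes and U2C+C66A (0.48). Total-count scaling called G6U+A43C+C46U+C66A+A69G alone, and U2C+G6A (0.20) was called alone without output replicate 22.

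Single substitutions had small effects in the reference background. G6U fell by 0.26 on the log2 scale (SD 0.09, n = 6), G6A fell by 0.20 (SD 0.09, n = 6) and G1A fell by 0.16 (SD 0.10, n = 6), below the reference in 6, 6 and 5 of 6 outputs. Their edgeR adjusted p-values were 0.00204, 0.014 and 0.0356. The other 11 did not pass, with values from -0.11 for C66U to 0.12 for U2C. Adjusted over the list alone, 1 of 14 was below and 0 above. In the authors' deposited table, G6U had the lowest natural-log fitness of the 14, -0.0403, and U2C the highest, 0.0175.

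The calls for single substitutions were not stable. With the replicate block U2G (log2 -0.09, edgeR adjusted p = 0.0404) and C66U (-0.11, 0.0181) were also below and U2C (0.12, 0.0234) was above, giving 5 below. Adjusted over the list alone, the block gave 3 below and 0 above. None of the 14 was below with TMM scaling, with size-factor scaling, or without input replicate 2, each of which gave 0. Under those scalings the values hardly moved (G6U -0.257 and -0.258, G6A -0.197 and -0.198, G1A -0.154 and -0.156) and their standard errors also held that of the reference, while without input replicate 2 they were -0.18, -0.15 and -0.11. G1A was also not called by DESeq2 (adjusted p = 0.089), without output replicate 12, 22 or 23 (edgeR adjusted p from 0.0527 to 0.0602), or with input 1 and its outputs alone (edgeR adjusted p = 0.0562). U2G was called without output replicate 21 (edgeR adjusted p = 0.0317). C66U stood at -0.13 with input 2 and its outputs alone, a fit whose 1 input gives no spread between inputs.

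Losses grew with the number of substitutions. The median log2 relative enrichment was -0.05 for the 14 genotypes with 1 substitution, -0.90 for 639 with 4, -1.47 for 989 with 6 and -1.95 for 323 with 8. Over the 6 outputs, each set against the mean of both inputs, these medians had SDs of 0.06, 0.10, 0.12 and 0.13. The share of genotypes below the reference went from 21.4% with 1 substitution to 80.6% with 4 and 94.4% with 8. It was 90.0% for the 90 genotypes with 9 and 90.9% for the 11 with 10. The median at 6 substitutions was -1.63 without input replicate 1, -1.23 without input replicate 2 and -1.01 with at least 100 reads in each input.

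**Figure D1:**
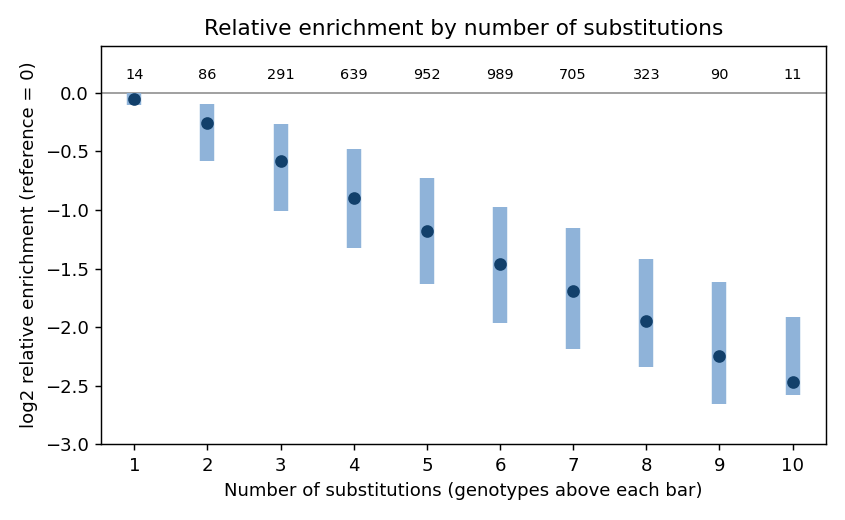
Log2 relative enrichment against the number of substitutions, with the median as a point, the quartiles as a bar and the number of genotypes above. The median is -0.05 with 1 substitution and -1.47 with 6.

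Whether a substitution acts alike in all backgrounds was asked next. All 14 substitutions rose in some backgrounds and fell in others by the edgeR-based contrasts. Of 20939 substitution and background combinations, 5.79% were called rises and 13.7% falls. U2C and C46U mostly rose: U2C had a median effect of 0.32 (log2, SD 0.01, n = 6) with 212 rises and 55 falls in 1137 backgrounds, and C46U 0.18 (SD 0.02, n = 6) with 136 rises and 34 falls in 1928. The other 12 had negative median effects, down to -0.50 for G6U (SD 0.02, n = 6), with 31 rises and 337 falls in 1351 backgrounds.

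Among the rest, A69G had a median of -0.40 with 40 rises and 320 falls, C71U -0.39 with 91 and 391, C66U -0.37 with 69 and 275, and C27U -0.37 with 45 and 297. G1A stood at -0.31 with 91 rises and 218 falls, A43C at -0.29 with 73 and 264, A70U at -0.26 with 55 and 158, and G6A at -0.24 with 83 and 174. C66A (-0.13, with 99 rises and 97 falls), A70G (-0.07, 86 and 126) and U2G (-0.05, 101 and 129) had the most even counts. With the replicate block 9.13% of tests were rises and 22.1% falls. The median effect of C66A was 0.17 where both inputs had at least 100 reads.

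**Figure D2:**
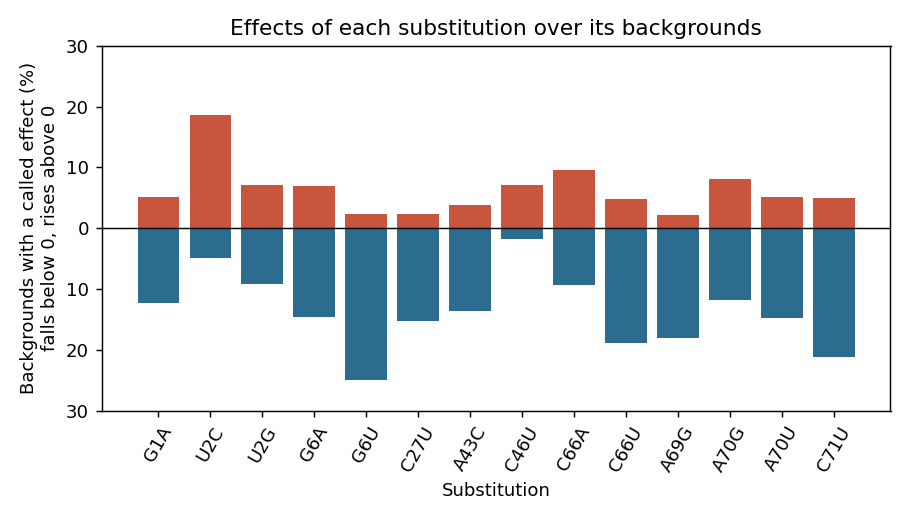
Percent of backgrounds in which each substitution was called to rise (above 0) or fall (below 0) in relative enrichment. U2C rises in 18.6% and falls in 4.84% of its backgrounds, and G6U rises in 2.29% and falls in 24.9%.

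Pairwise interactions went both ways. Of 46207 tests over 87 pairs, 6.95% were called positive and 5.89% negative, and 86 pairs were called in both directions. The average over backgrounds passed the threshold as positive for 30 pairs and as negative for 21. That test used the combined measurement errors alone, so it does not measure the spread over backgrounds. With the replicate block 12.1% were positive and 10.9% negative, with limma 15.1% and 13.97%, with at least 100 reads in each input 20.5% and 19.9%, and without input replicate 2 the shares were 3.24% and 2.63%.

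Pairs on the facing list had more positive interactions than other pairs. The 10 facing pairs averaged 0.28 (log2, SD 0.18 over pairs) and the 77 others 0.02 (SD 0.12), a difference of 0.27 (permutation p = 1e-05, the smallest the permutations can give). With the acceptor stem alone the 9 facing pairs averaged 0.30, and the difference was 0.28 (permutation p = 1e-05). With at least 100 reads in each input the difference was 0.54 by the fixed list (permutation p = 2e-05) and 0.60 by the acceptor stem alone (permutation p = 1e-05). U2C+A70G stood highest at 0.55 (SD 0.08, n = 6), followed by G6U+C66A at 0.52 (0.10) and G6A+C66U at 0.47 (0.07), each positive in 6 of 6 outputs. G1A+C71U was at 0.30, U2G+A70U at 0.25, G6U+C66U at 0.23 and U2C+A70U at 0.23.

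Lower on the list were G6A+C66A at 0.12 (SD 0.08, n = 6), C27U+A43C at 0.11 (SD 0.02, n = 6) and U2G+A70G at 0.05 (SD 0.04, n = 6). The last did not pass (adjusted p = 0.118 from the combined measurement errors of the edgeR fit). C27U+A43C is the entry of the list that is not a stem pair in the deposited sequence, and it turned to -0.058 with at least 100 reads in each input. G6A+C66A turned to -0.029 with input 1 and its outputs alone. In the reference background itself 5 of the 10 facing pairs, or 4 of the 9 in the acceptor stem, had a negative interaction and 5 a positive one, and 0 passed (lowest adjusted p = 0.158 from the edgeR-based contrasts). There G6U+C66A stood at 0.35 ± 0.20 (SE), G6A+C66U at 0.29 ± 0.16 (SE), U2C+A70G at -0.08 ± 0.12 (SE) and G6A+C66A at -0.79 ± 0.34 (SE), the highest and lowest of the 10 among them.

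**Figure D3:**
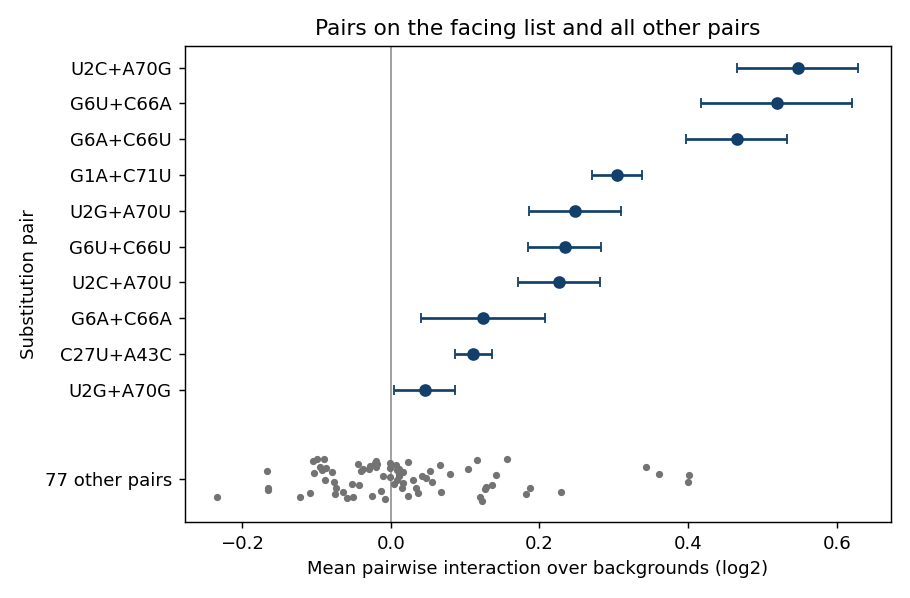
Mean pairwise interaction over backgrounds (log2) for the 10 pairs on the facing list, with the SD over 6 outputs, and for 77 other pairs as points. U2C+A70G is highest at 0.55, and the other pairs average 0.02.

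Outside the facing list the most positive means were those of U2C+G6U (0.40, SD 0.04, n = 6), U2C+G6A (0.40), C66U+A70G (0.36), A69G+A70G (0.34) and C66A+A70G (0.23). The most negative were A70U+C71U (-0.23, SD 0.05, n = 6), A43C+C66A (-0.17), G1A+U2G (-0.17), A43C+C66U (-0.17) and G1A+C27U (-0.12). All 10 kept their sign in 6 of 6 outputs. A69G+A70G turned to -0.043 with at least 100 reads in each input.

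Interactions changed with another substitution as well. Of 57339 tests over 316 triples, 5.76% were called positive and 5.40% negative. C66U+A69G+A70U had the largest absolute mean, 0.56 (SD 0.05, n = 6) over 132 backgrounds, followed by A69G+A70U+C71U at -0.51 (SD 0.12, n = 6) over 99 and C66A+A69G+A70U at 0.47 (SD 0.19, n = 6) over 46. With the replicate block 22.1% of tests were called in either direction, against 11.2%; the share was 28.01% with limma, 37.2% with at least 100 reads in each input and 4.08% without input replicate 2. C66A+A69G+A70U turned to -0.66 where the mean output count was at least 10.

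Additive effects of the 14 substitutions explained 53.1% of the variance of genotypes held out of the fit. Adding pairwise terms raised this to 63.3%, and adding third-order terms gave 63.4%. Fitted to each output alone, the mean R squared was 0.435, 0.521 and 0.5145 (n = 6). There the step to pairwise terms was 0.0858 ± 0.0091 (SD, n = 6), a rise in 6 of 6 outputs, and the step to third-order terms was -0.0064 ± 0.0051 (SD, n = 6), a rise in 1 of 6. With at least 100 reads in each input R squared over all outputs was 0.360, 0.471 and 0.441. Measurement error made up 12% of the variance of the fitted values.

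Genotypes without mismatched stem pairs had a higher median relative enrichment. The fixed list counts C27 with A43 as a mismatched pair, so the reference itself has 1 by that list. Its genotypes with 0 all carry C27U. By the fixed list the median was -0.71 for 192 genotypes with 0 mismatched pairs (SD 0.13, n = 6) and -1.23 for 1040 with 1, with -1.32, -1.31 and -1.30 at 2, 3 and 4. For the acceptor stem alone it was -0.62 for 764 genotypes with 0 (SD 0.11, n = 6), then -1.35, -1.32 and -1.34 at 1, 2 and 3. Lower quartiles hardly differed by the fixed list (-1.85 at 0 and -1.84 at 1), and the shares of genotypes not called below the reference were 16.7% with 0 mismatched pairs and 21.2%, 9.98%, 13.6% and 20.55% with 1, 2, 3 and 4; by the acceptor stem alone they were 30.6% with 0 and 9.03%, 11.9% and 18.4% with 1, 2 and 3. With at least 100 reads in each input the median at 0 exceeded that of all others by 0.23, against 0.59, by the fixed list and by 0.59, against 0.72, by the acceptor stem alone. No test was made of these medians. Genotypes in which substitutions restore every facing acceptor pair, G1A+U2C+G6A+C66U+A70G+C71U and G1A+U2C+G6U+C66A+A70G+C71U, stood at -0.07 ± 0.15 and -0.07 ± 0.14 (SD, n = 6; edgeR adjusted p = 0.656 and 0.622).

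With C27U added, these became -0.25 ± 0.31 and -0.33 ± 0.12 (SD, n = 6; edgeR adjusted p = 0.251 and 0.0443). With the replicate block the former passed as below the reference (edgeR adjusted p = 0.027). It also passed with limma (adjusted p = 0.00421), which counted outputs that share an input as independent. The latter was not called with TMM or size-factor scaling (edgeR adjusted p = 0.0623 and 0.0729), without input replicate 2 (edgeR adjusted p = 0.339), without output replicate 11, 12, 13 or 23 (edgeR adjusted p from 0.0673 to 0.0795), or with either input and its outputs alone (edgeR adjusted p = 0.0905 and 0.0633).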

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

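Of the tests weighed here, those of measurement noise, of a monotone scale against effects in both directions, of restored pairing and of culture doublings were chosen after the result was seen. Among 62 values measured in each of the 6 outputs, 2 had an output far from the others, against 3.1 by chance. Both were output replicate 21. The relative enrichment of G6A was -0.0195 there and -0.25 to -0.23 in the other 5. The median relative enrichment of all genotypes was -1.06 there and -1.35 to -1.25 in the others. These values were set against the mean of both inputs. By the mean over genotypes, output replicate 21 was then at -1.16 and the others at -1.44 to -1.32. Against its own input it was at -1.32, inside the range of the others, -1.49 to -1.20.

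All 14 substitutions were called up in some backgrounds and down in others, against 0 to 3 in simulated data without interaction. The simulations called only 0.01%, 5.62% and 1.76% of effect tests, against 19.5% in the data, so fewer calls could go either way there. Of 1126 calls against a substitution's main direction made with input 1 and its outputs, 96.00% had the same sign with input 2 and its outputs, which argues against measurement noise. A monotone scale over additive effects cannot turn a sign, yet 14 substitutions were called up in both sets and down in both. With at least 100 reads in each input, 14 were still called in both directions, which argues against genotypes with few reads. Of 46207 pairwise tests 12.8% were called, 97.15% of the calls made with input 1 and its outputs had the same sign with input 2, and simulated additive data gave 0%, consistent with effects that depend on the other bases present, a hypothesis found and tested on the same data.

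Facing pairs had more positive interactions than others. After a monotone curve over the additive score was removed the difference by the fixed list was 0.2656, unchanged to 4 decimals, because the curve averaged -0.0057 over facing and over other pairs, with single pairs between -0.063 and 0.077, and for the acceptor stem alone it was 0.2809, against 0.2834 before; this argues against such a scale as the cause. The 4 acceptor pairs that form a Watson-Crick pair together averaged 0.46 and the 5 that do not 0.18. The exact permutation p was 0.0079, the smallest that 126 splits can give, and restored pairing would give such a difference. Of the 5, U2G+A70U (0.25) was highest and forms a G-U pair, so the split is not of pairing against no pairing. Pairs share substitutions and are not independent. In level, only the restored pair C with G at positions 2 and 70 (-0.63) was above every mismatch there (highest C with A, -0.88). For positions 1 and 71, A with U (-1.55) was below A with C (-1.28). For positions 6 and 66, U with A (-1.16) and A with U (-1.18) were below G with A (-0.9996). Both were above U with C (-1.42) and differed from A with C (-1.14) by less than the SD. Restored pairing thus stays a hypothesis.

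Losses looked smaller with input 1 than with input 2, with mean log2 relative enrichment of -1.21 and -1.40, each against its own input; with at least 100 reads in each input they were -0.84 and -0.91, a difference of 0.06. Set against the mean of both inputs the difference was -0.1322, in the other direction, in place of 0.19, consistent with input libraries of different composition. The number of culture doublings was higher by 0.1381 in the outputs of input 1, which argues against fewer doublings as the cause. No biological explanation was tested.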

How the results depend on the processing

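The acceptor stem alone and each input with its own outputs were chosen after seeing the data. The difference of facing and other pairs stayed positive with permutation p under 0.05 in all 21 alternatives run for it, and for the acceptor stem alone, from 0.20 to 0.60, in all 20 others; all 14 substitutions had effects in both directions in the 19 run for that count. Of 4100 genotypes 1314 had at least 100 reads in each input. Where a cause is not named, the cause was not tested.

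With at least 100 reads in each input, fewer genotypes were tested: 977 were below the reference, the facing difference was 0.54, 20.5% of pairwise tests were positive and 19.9% negative, and 37.2% of third-order tests were called. R squared was 0.360, 0.471 and 0.441 for the additive, pairwise and third-order models, the median at 6 substitutions -1.01, and the gap of 0 to more mismatched pairs 0.23. With a mean output count of at least 10, R squared was 0.510, 0.599 and 0.597 and the median at 6 substitutions -1.32.

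Genotypes above the reference numbered 1 with total-count scaling, 5 with limma and 5 with the replicate block. Substitutions below it alone numbered 0 with TMM, 0 with size factors and 5 with the replicate block. Limma called 15.1% of pairwise tests positive and 13.97% negative and 28.01% of third-order tests; the replicate block called 12.1%, 10.9% and 22.1%. Beyond these and the calls printed with the results, the block changed no other call of a named result.

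Input 1 with its outputs gave R squared of 0.466, 0.549 and 0.544, a median at 6 substitutions of -1.33 and a mismatch gap of 0.46. Input 2 with its outputs gave 0.510, 0.613 and 0.613 and a gap of 0.77. The acceptor stem alone gave a gap of 0.72, against 0.59, and 0.57 to 0.86 under the other alternatives.

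Leaving out each library in turn gave 0 to 1 genotypes above the reference and 2911 to 3569 below, and 0 to 4 single substitutions below. Pairwise tests were 3.24% to 6.83% positive and 2.63% to 5.77% negative, and third-order calls 4.08% to 10.8%. R squared ran from 0.466 to 0.531, 0.552 to 0.631 and 0.548 to 0.632, the median at 6 substitutions from -1.63 to -1.23 and the mismatch gap from 0.48 to 0.68. The lowest shares and R squared came without input replicate 2.

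Signs turned for 5 of the 1101 values of named results under alternatives: C66A to 0.17, C27U+A43C to -0.058 and A69G+A70G to -0.043 with at least 100 reads, C66A+A69G+A70U to -0.66 with a mean output count of at least 10, and G6A+C66A to -0.029 with input 1 alone. Of the others 977 stayed, 89 moved by over 1 SD, 23 lost their call and 7 gained one.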

Other observations

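The base combinations at facing acceptor positions were compared after the results were seen, as means over backgrounds in which all combinations were measured. At positions 1 and 71, over 751 backgrounds, G with C stood at -0.81 ± 0.06 (SD, n = 6), A with C at -1.28 ± 0.11, G with U at -1.38 ± 0.09 and A with U at -1.55 ± 0.12. The A-U pair was thus lowest although it can pair. At positions 2 and 70, over 241 backgrounds, C with G was highest at -0.63 ± 0.09. The mismatch C with A (-0.88 ± 0.11) and the reference pair U with A (-0.91 ± 0.08) differed by less than the SD, and U with U was lowest at -1.40 ± 0.08. The wobble pairs U with G and G with U stood at -1.19 ± 0.10 and -1.26 ± 0.09. The remaining mismatches stood at -1.09 ± 0.09 (G with A), -1.15 ± 0.11 (C with U) and -1.31 ± 0.10 (G with G). At positions 6 and 66, over 219 backgrounds, G with C stood at -0.71 ± 0.07, U with A at -1.16 ± 0.10, A with U at -1.18 ± 0.07 and U with U at -1.74 ± 0.07. The mismatches G with A (-1.0 ± 0.12) and A with C (-1.14 ± 0.08) were not below these A-U and U-A pairs, while U with C (-1.42 ± 0.08) was. The mismatch A with A (-1.31 ± 0.15) and the wobble pair G with U (-1.24 ± 0.09) were below them by less than their own SD.

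Genotypes with no mismatched acceptor pair differed by the makeup of the 4 varied pairs. The median was -1.82 ± 0.14 (SD, n = 6) for 285 genotypes with 0 G-C pairs, -0.42 ± 0.09 for 336 with 1 and -0.14 ± 0.06 for 127 with 2. By wobble pairs it was -0.13 ± 0.04 for 95 genotypes with 0 G-U pairs, -0.25 ± 0.08 for 270 with 1, -1.29 ± 0.12 for 271 with 2 and -1.75 ± 0.12 for 112 with 3. Among genotypes with 6 substitutions, the medians were -1.89 for 75 with 0 G-C pairs, -0.79 for 63 with 1 and -0.18 for 27 with 2. At that number of substitutions, 166 genotypes without a mismatched pair had a median of -1.06 ± 0.15 and 823 with a mismatch -1.5 ± 0.11. The counts of G-C and G-U pairs were not independent: genotypes with more G-U pairs tended to have fewer G-C pairs. How far the median differed by 1 kind depended on the count of the other. With 0 G-U pairs the medians were -0.43, -0.14, -0.09 and -0.06 for 0, 1, 2 and 3 G-C pairs, with 1 G-U pair -1.35, -0.25, -0.14 and -0.17, and with 2 G-U pairs -1.93, -0.79 and -0.19 for 0, 1 and 2 G-C pairs. With 0 G-C pairs they were -0.43, -1.35, -1.93, -1.96 and -1.95 for 0 to 4 G-U pairs. With 1 G-C pair they were -0.14, -0.25, -0.79 and -1.36 for 0, 1, 2 and 3 G-U pairs, and with 2 G-C pairs -0.09, -0.14 and -0.19 for 0, 1 and 2, where neighbouring medians differed by less than the SD at 1 G-U pair (0.07, n = 6). No p-value was computed for these medians.

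Values from the 2 sets of libraries, each input with its own outputs, had a Pearson correlation of 0.830 across 4100 genotypes and 0.961 across 1314 with at least 100 reads in each input. Genotypes are not independent replicates. Mean pairwise interactions correlated at 0.933 across pairs and mean third-order interactions at 0.796 across triples. The authors' deposited fitness correlated with the fitted relative enrichment at 0.993 across genotypes.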
